A study of Mus musculus with 36 samples.

How the data were processed

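RNA was sequenced from 2 tissues of aged wild-type C57BL/6 mice that drank either CP2, which the labels describe as an inhibitor of mitochondrial complex I, or vehicle. Per the labels' protocols, CP2 was given at 25 mg/kg/day in water with 0.1% PEG from 21 months of age, vehicle animals drank 0.1% PEG alone, and the series design gives 26 months as the age of the animals profiled. The brain piece was a slice through cortex and hippocampus, and the fat was the inguinal depot. Libraries were made from 200 ng of total RNA with a TruSeq kit that does not record the strand of a transcript, and read as pairs of 101 bp on an Illumina HiSeq instrument.

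The deposited table gives, for each of 36 libraries, a whole-number count per Ensembl gene and a value in FPKM, along with each gene's position, length and biotype. Per the submitters' processing notes, the tools were bcl2fastq, STAR 2.6.1c and featureCounts of the Subread package, on build mm10. The annotation release, the strand setting and any filter of reads are not given in the sources used here. The counts deposited by the authors carry no normalization and were the only values tested. The FPKM values that the authors deposited were used as a check: within each library they were proportional to the count divided by the gene length, within 0.729% for 99% of the values. The sum of the gene counts was 0.355 to 0.403 of the total on which the FPKM values were based, so the FPKM base held more than the reads counted to genes. The table holds 43346 genes, among them 37 encoded by the mitochondrial genome, and these 37 had 0 reads in all 36 libraries. Transcripts of the mitochondrial genome could therefore not be compared, and the list of them drawn up beforehand was not tested.

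Total counts per library ran from 35 to 56.4 M (mega). Across the 20 brain libraries the total was 37.4 to 53.0 M and the 10 highest genes took 2.72% to 3.33% of the counts, against 35 to 56.4 M and 7.06% to 14.9% in the 16 fat libraries. No 2 count columns were identical. Because the library kit does not record the strand, genes that overlap on opposite strands cannot be told apart, and members of near-identical families (immunoglobulin segments, caseins and other paralogs) are uncertain.

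Libraries were grouped by tissue, sex and treatment as the labels give them, in 8 groups of 3 to 5. The number in a sample's title was taken as its replicate number. The titles hold 28 numbers, 8 of which occur in both tissues, each with the same sex and treatment in both, so a shared number was read as the same animal, although nothing states it. The fits with the number as a block were planned before the data were examined, but this reading was settled only after the results were seen. Over 17344 genes the brain and fat libraries with a shared number correlated at -0.0764 to 0.185, and 2 of 8 matched their own number best. Nothing in the labels says whether the libraries of a group came from separate animals, so the p-values measure the spread between these libraries, part of which may be technical. Titles also carry an L number from 1 to 6, whose meaning is not stated. In brain males it was nearly tied to treatment: vehicle libraries had L numbers 1 and 2, and 4 of the 5 CP2 libraries had L number 6. The remaining CP2 library, s581, had L number 2, so brain fits with the L number rest on s581 for the male CP2 difference. Among brain vehicle libraries the L number was split by sex, with 1 and 2 in males and 4 to 6 in females. In fat females only vehicle s442 shared an L number, 1, with female CP2 libraries.

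Each tissue was fitted with edgeR 4.0.16 (R 4.3.3) in 1 model over its 4 groups, after filterByExpr and TMM scaling, with robust quasi-likelihood dispersions. The brain fit tested 19316 genes with a biological coefficient of variation of 0.170 and 16 residual degrees of freedom, and the fat fit 19769 genes with 0.500 and 12. A model over all 36 libraries (22012 genes, 0.364, 28 residual degrees of freedom) gave the difference of the CP2 effect between tissues. Contrasts were CP2 against vehicle in each sex and averaged over the sexes, the female CP2 effect minus the male one, and female against male vehicle. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. Fold changes are on the log2 scale with standard errors derived from the quasi-likelihood F statistic. CPM values use TMM-scaled library sizes.

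In total 55 gene lists were drawn up from general knowledge before the data were examined, as were the groups, the models, the rule for naming genes and most alternatives. Of these, 40 applied to brain and 38 to fat, and 1050 of the 1071 listed symbols were found in the table. Lists with at least 3 measured genes were tested with camera on voom values (limma 3.58.1) at a preset correlation between genes of 0.01, again with the correlation estimated per list, and with fry, each adjusted over the lists of a comparison. A library's list score is the mean log2 CPM of the members. When libraries were regrouped at random, camera with the preset correlation called a median of 13 to 15 lists in the comparisons within a tissue, against 7 to 20 in the real grouping. A call at the preset correlation alone is therefore weak evidence, and the p with an estimated correlation stands beside it.

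Named genes follow a rule: in each CP2 comparison the 10 genes per direction with the smallest p among those past the threshold with a mean of at least 1 CPM, leaving out predicted genes, or the 5 smallest p-values where fewer than 5 passed; 5 per direction for interactions and sex differences; and the members of a list with the 3 smallest p-values. Xist and the Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty are named as checks of the labels. Not all of these are printed, and 4732419C18Rik, a predicted gene outside the rule, was added after its values were seen. Which lists are described, and which genes are given as levels in CPM, was decided after the list results had been seen, as were the counts of list members without brain male vehicle s620 or fat male CP2 s530, so the lists described are those that stood out among all lists tested, except the mitochondrial complexes in brain.

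The pipeline was tested on simulated counts drawn from the means, library sizes and dispersions of each tissue, with 66 or 67 genes changed at each of 3 fold sizes in the male CP2 libraries. In the brain simulation (19151 genes) 59.7% of 1.5-fold, 91.0% of 2-fold and 100% of 4-fold changes in males were recovered, and 8 of 175 calls were unchanged genes. In the fat simulation (19476 genes) these shares were 1.49%, 17.9% and 71.2%, with 2 of 62 calls unchanged. Females, unchanged in both simulations, gave 0 calls. In fat, most changes of 2-fold or less would therefore be missed gene by gene at this number of libraries. The simulation assumes independent libraries and does not copy differences in tissue content.

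Alternatives were RLE size factors, DESeq2 1.42.0, no filter on low counts, a filter of at least 1 CPM in no fewer libraries than fall below it, the L number as a factor, limma-voom with sample quality weights, 1 surrogate variable (sva 3.50.0), a fit of the compared groups alone, camera with an estimated correlation, and leaving out each replicate in turn. For the comparison of tissues, the replicate number was also used as a block. Alternatives chosen after seeing the data were a covariate for brain region content, covariates for muscle, mammary and B cell transcripts in fat, and leaving out fat male vehicle s540 and fat male CP2 s571 together. Brain male CP2 s581 was also singled out after seeing the data, and its omission is covered by leaving out each replicate in turn.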

Results

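Transcripts were counted in 20 brain and 16 inguinal fat libraries from aged male and female mice given CP2 or vehicle in the drinking water. Brain was represented by 5 libraries for each sex and treatment. Fat was represented by 5 male vehicle, 4 male CP2, 4 female vehicle and 3 female CP2 libraries. Total counts ran from 37.4 to 53.0 M (mega) per library in brain and from 35 to 56.4 M in fat. The group means were between 40.6 ± 3.36 M (SD, n = 5, brain female vehicle) and 47.1 ± 4.28 M (n = 5, brain female CP2). Values are given as log2 fold changes ± SE from edgeR, or as CPM ± SD over the n libraries of a group. Libraries are named by group and by the s number in their title.

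The sex given for each library was checked with sex-linked transcripts. Xist, the RNA that coats the inactive X chromosome, was at 785 to 1250 CPM in the 10 female brain libraries and 1218 to 1723 CPM in the 7 female fat libraries. In males it was at 0.0198 to 0.917 CPM in brain and 0.0672 to 6.52 CPM in fat. The Y-linked Ddx3y was at 75.1 to 141 CPM in male brain and 86.9 to 166 CPM in male fat, with 0 to 2 counts in female brain and 0 counts in female fat. Every library matched the sex in its labels.

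The first question was whether CP2 changed transcript levels in the brain, averaged over the sexes. No gene passed the threshold, and the nuclear genes of the respiratory chain, the target of the compound, lay near 0. Of 36 complex I subunits 17 were higher, with a median log2 change of -0.003, a mean of 0.005 and a camera direction up (adjusted p = 0.960, and 0.994 with an estimated correlation), and of 35 subunits of complexes III to V 18 were higher, with a median of 0.01 (adjusted p = 0.849, and 0.994 with an estimated correlation). In both lists 0 members passed over all genes and 0 adjusted over the list alone. Ndufv1, a complex I subunit, had a log2 change of 0.12 ± 0.07. Genes with the smallest p included Tle6 (0.35 ± 0.10) and Masp1 (0.28 ± 0.08) on the higher side and Eomes (-1.25 ± 0.39) and Meis1 (-0.26 ± 0.08) on the lower, all with an adjusted p of 0.928.

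Endothelial and pericyte markers were higher for 17 of 18 members, with a median of 0.19 (camera adjusted p = 0.000202, adjusted p = 0.962 with an estimated correlation). Members included Tek (0.27 ± 0.12), the angiopoietin receptor. The list score was 4.75 in male CP2 s581, 3.80 to 4.31 in the other male CP2 libraries and 3.92 to 4.38 in male vehicle. Striatal markers were lower for all but 1 of 14 members, with a median of -0.20 (adjusted p = 0.00116, and 0.962 with an estimated correlation), and -0.061 without female vehicle s643, where the call was lost. Neither list had a member past the threshold, over all genes or adjusted over the list alone. edgeR called 0 of 19316 genes, with 662 at an unadjusted p under 0.05 where 965.8 would come by chance; DESeq2 and limma-voom also called 0, and the fit with the L number called 4.

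In brain of males, CP2 went with lower levels of transcripts typical of thalamus and hypothalamus. Ebf3, a transcription factor of the early B cell factor family (ENSMUSG00000010476, mm10 chromosome 7, 137193673 to 137314445), fell from 7.74 ± 2.27 to 1.93 ± 0.804 CPM (n = 5 and 5), a log2 change of -2.01 ± 0.31 (edgeR adjusted p = 0.0452), and was the 1 gene called. All 20 thalamic and hypothalamic markers were lower, with a median of -1.59. Past the threshold were 0 over all genes and 13 adjusted over the list alone (camera adjusted p = 2.45e-13, adjusted p = 0.819 with an estimated correlation, fry adjusted p = 0.351). Among them were Rgs16, a regulator of G protein signalling (-0.97 ± 0.23), the neuropeptide gene Gal (-1.83 ± 0.47) and Calb2, which encodes calretinin (-1.59 ± 0.40). Outside the lists, the serotonin receptor gene Htr7 (-0.70 ± 0.14), Arl4c (-0.39 ± 0.08), Arhgap24 (-0.62 ± 0.13) and Lhx1 (-2.02 ± 0.43) had an adjusted p of 0.174, as did Ccnf on the higher side (0.58 ± 0.13).

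Striatal markers were higher in males for all 14 members, with a median of 0.47, 0 past the threshold over all genes or adjusted over the list alone (adjusted p = 0.000257, and adjusted p = 0.922 with an estimated correlation). They included the dopamine receptor gene Drd1a (0.58 ± 0.26), Rgs9 (0.66 ± 0.30) and Tac1 (0.61 ± 0.29), and the first of these averaged 137 ± 53.7 CPM with CP2 and 91.4 ± 19.99 with vehicle. Drd1a was at 215 CPM in male CP2 s583, 78.5 to 160 in the other male CP2 libraries and 62.2 to 118 in male vehicle. Excitatory synapse genes were higher for 22 of 24 members, with a median of 0.22 and 0 calls either way (adjusted p = 0.000257, and adjusted p = 0.922 with an estimated correlation). Gria2 (0.36 ± 0.12) and Grin2a (0.46 ± 0.17) were among these, while Slc17a6, the glutamate transporter gene that is also on the thalamic list, was lower (-1.23 ± 0.39). Oligodendrocyte and myelin genes had a median of -0.14, with 1 of 18 higher and 0 calls either way (adjusted p = 0.00366, and adjusted p = 0.922 with an estimated correlation). Members included Tspan2 (-0.39 ± 0.13), and without male CP2 s583 the median was -0.070 and the call was lost.

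The male brain count rested on the choice of tool and on single libraries. At an unadjusted p under 0.05 there were 2036 genes, DESeq2 called 82 and limma-voom with quality weights 787, while 0 were called without a low-count filter, with a stricter filter, with a surrogate variable, with the 2 groups alone or with the region score as a covariate, and 6 with the L number. Leaving out male vehicle s620, which had the lowest thalamic score of its group (1.88 against 3.77 to 4.52), gave 156 genes (16 higher, 140 lower), leaving out male CP2 s530 gave 2, and the count was 0 without any other library except female vehicle s643, without which it was 1. With the region score the striatal median in males turned to -0.19, and with the L number the oligodendrocyte median turned to 0.14. The fit with the L number rests on male CP2 s581 here, because no other male CP2 library shared an L number with male vehicle.

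In brain of females the same marker groups lay the other way. Striatal markers were lower for all but 1 of 14 members, with a median of -0.99. Of these, 0 passed over all genes and 13 adjusted over the list alone (camera adjusted p = 5.05e-14, adjusted p = 0.419 with an estimated correlation). Drd1a averaged 39.6 ± 4.04 CPM with CP2 and 90.9 ± 39.5 with vehicle (n = 5 and 5), a log2 change of -1.20 ± 0.27, and Ppp1r1b, which encodes DARPP-32, was lower as well (-1.0 ± 0.25). Thalamic and hypothalamic markers were higher for 19 of 20 members, with a median of 0.85. Members past the threshold numbered 0 over all genes and 7 adjusted over the list alone (adjusted p = 3.88e-10, adjusted p = 0.419 with an estimated correlation). Members included Plekhg1 (0.92 ± 0.22) and Lef1 (0.81 ± 0.23). Female vehicle s643 had a score of 1.97 for this list, against 3.56 to 4.62 in the other female vehicle libraries.

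Myelin genes were higher in females for 17 of 18 members, with a median of 0.33. The threshold was passed by 0 over all genes and 5 adjusted over the list alone (adjusted p = 1.73e-06, adjusted p = 0.557 with an estimated correlation). They included Opalin (0.76 ± 0.24), Mag (0.46 ± 0.15) and Cnp (0.37 ± 0.13), all of the myelin sheath. In female CP2 s492 Opalin was at 86.2 CPM and the list score at 8.32. The other female CP2 libraries had 33.3 to 54.6 CPM and scores of 7.76 to 8.01. Genes of disease-associated microglia were higher for 20 of 21 members (median 0.27, adjusted p = 9.15e-05, adjusted p = 0.746 with an estimated correlation). Members included Axl (0.26 ± 0.09) and Gpnmb (0.79 ± 0.33). The score of this list was 6.78 in female CP2 s492, 5.76 to 6.29 in the other female CP2 libraries and 5.66 to 6.33 in female vehicle. Endothelial and pericyte markers were higher for 18 of 18 (median 0.24, adjusted p = 0.000136, adjusted p = 0.746 with an estimated correlation). Members included Notch3 (0.64 ± 0.21), and neither of these 2 lists had a member past the threshold over all genes or adjusted over the list alone. All 4 measured pituitary transcripts were higher (median 2.46, adjusted p = 0.0270, adjusted p = 0.557 with an estimated correlation), 0 past the threshold over all genes and 1 adjusted over the list alone; the call was lost without female vehicle s643 (3.04) or s642 (3.27) or female CP2 s491 (2.32) or s664 (2.29). The pituitary hormone gene Prl stood at 93.2 ± 121 CPM with CP2 and 5.83 ± 7.63 with vehicle.

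edgeR called 0 genes in female brain, with 1910 at an unadjusted p under 0.05. DESeq2 called 45, limma-voom with quality weights 98, and leaving out female vehicle s640 gave 18. The region score as a covariate turned the thalamic median to -0.11, and moved the microglial median to 0.12 and the pituitary one to 0.92, and with the L number the endothelial median was 0.11.

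The difference between the sexes was tested directly. Ebf3 was the 1 gene called: its female CP2 effect exceeded the male one by 2.98 ± 0.44 (edgeR adjusted p = 0.0162), with 7.30 ± 1.70 CPM in CP2 females and 3.71 ± 1.46 in vehicle females (n = 5 each). Thalamic and hypothalamic markers differed in the same direction for 20 of 20 members, with a median difference of 1.98. In this list 0 passed over all genes and 15 adjusted over the list alone (camera adjusted p = 4.83e-16, adjusted p = 0.503 with an estimated correlation, fry adjusted p = 0.0487). Tcf7l2, a transcription factor of thalamic neurons, differed by 2.56 ± 0.56 and Rgs16 by 1.62 ± 0.33. Striatal markers differed the other way for all 14 members, with a median of -1.47 and 13 adjusted over the list alone against 0 over all genes (adjusted p = 4.85e-12, adjusted p = 0.692 with an estimated correlation). Members included Drd1a (-1.78 ± 0.37). Myelin genes had a median difference of 0.48, 17 of 18 of them positive, with 8 past the threshold adjusted over the list alone and 0 over all genes (adjusted p = 1.84e-06, adjusted p = 0.857 with an estimated correlation). Members included Opalin (1.21 ± 0.34).

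**Figure D1:**
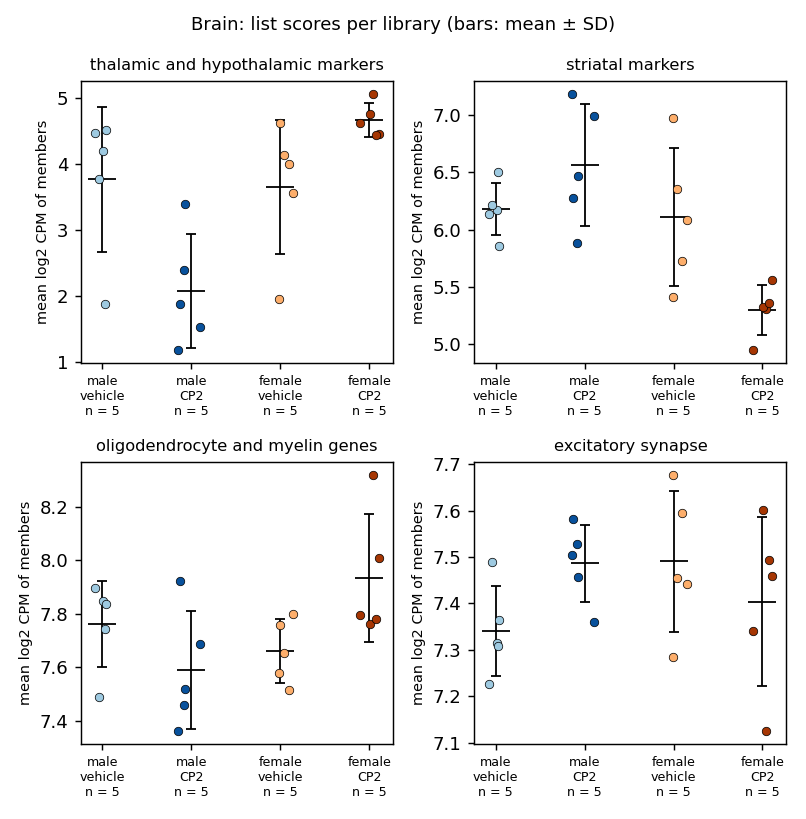
Scores of 4 gene lists (mean log2 CPM of the members, vertical axis) in each of the 20 brain libraries by group, with bars for the group mean and SD. The thalamic and hypothalamic score averaged 2.08 in CP2 males and 4.67 in CP2 females, against 3.77 and 3.66 in the vehicle groups.

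Further genes of this comparison had an adjusted p of 0.0505, among them Tox (0.94 ± 0.16) and Arhgap24 (0.96 ± 0.18) on the positive side and Ccng2 (-0.69 ± 0.13) and Slc25a14, a mitochondrial carrier gene, (-0.51 ± 0.10) on the negative. The count of 1 moved with tool and libraries: DESeq2 called 707, limma-voom 2028, a surrogate variable 327, the stricter filter 64, the L number 2, and no filter or the region score 0. It was 809 without male vehicle s620, 356 without female vehicle s640, 236 without male CP2 s581, 211 without male CP2 s530, 58 without female CP2 s491, 2 without female vehicle s631, female CP2 s664 or male CP2 s583, and 0 without male vehicle s621, female vehicle s641, female CP2 s492, male CP2 s571 or male CP2 s612. With the region score the striatal and thalamic medians were -0.05 and 0.28, and the myelin median was 0.13 with the L number.

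Over 15542 brain genes, male and female CP2 changes were inversely related (Pearson's r = -0.375, Spearman's rho = -0.331), a correlation across genes, which are not independent replicates. It was -0.115 with the L number and -0.240 with the region score.

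In inguinal fat averaged over the sexes, genes of mitochondrial respiration and of fatty acid metabolism were higher with CP2, and immediate early genes fell. Of 36 nuclear complex I subunits 36 were higher (median 0.43). Calls were 0 over all genes and 26 adjusted over the list alone (camera adjusted p = 1.03e-27, adjusted p = 0.167 with an estimated correlation, fry adjusted p = 0.0529). Of 35 subunits of complexes III to V 35 were higher (median 0.47). Past the threshold were 0 over all genes and 32 adjusted over the list alone (adjusted p = 6.35e-30, adjusted p = 0.167 with an estimated correlation). The complex I subunit Ndufa6 was higher by 0.47 ± 0.08 and Uqcrfs1, the iron-sulfur subunit of complex III, by 0.68 ± 0.15. Lipogenesis genes had a median of 1.12, with 23 of 24 higher. Of these, 0 passed over all genes and 15 adjusted over the list alone (adjusted p = 5.31e-18, adjusted p = 0.132 with an estimated correlation). Lipolysis and fatty acid oxidation genes had a median of 0.50, with 25 of 26 higher. Members past the threshold numbered 0 over all genes and 15 adjusted over the list alone (adjusted p = 4.03e-16, adjusted p = 0.132 with an estimated correlation).

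Among these, the acetyl-CoA carboxylase gene Acacb was at 1.33 ± 0.25, the mitochondrial citrate carrier gene Slc25a1 at 1.68 ± 0.36, the acyl-CoA dehydrogenase gene Acadvl at 0.77 ± 0.14 and Cpt2, of the carnitine shuttle, at 0.64 ± 0.15. Thermogenic and beige adipocyte genes were higher for 14 of 20 members (median 0.50). The threshold was passed by 0 over all genes and 9 adjusted over the list alone (adjusted p = 5.26e-07, adjusted p = 0.177 with an estimated correlation). Members included the potassium channel gene Kcnk3 (1.62 ± 0.29). Genes of mitochondrial biogenesis and AMPK had a median of 0.11, with 16 of 20 higher. In this list 0 passed over all genes and 1 adjusted over the list alone (adjusted p = 0.00176, adjusted p = 0.132 with an estimated correlation). Members included Ppargc1b (0.70 ± 0.18). Adipocyte identity genes had a median of 0.24, with 16 of 20 higher and 0 calls either way (adjusted p = 0.00498, adjusted p = 0.765 with an estimated correlation); their median was 0.02 with the L number and 0.06 with the composition covariates, and the call was also lost without female vehicle s463 (0.14) or female CP2 s454 (0.11).

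All 21 immediate early genes were lower, with a median of -0.59, 0 past the threshold over all genes and 4 adjusted over the list alone, and the call held with an estimated correlation (camera adjusted p = 3.31e-09 preset and 0.0164 estimated, fry adjusted p = 0.00650). Dusp1, a phosphatase that acts on MAP kinases, was at -0.77 ± 0.23 and the transcription factor gene Jun at -0.59 ± 0.18. Smooth muscle and Schwann cell markers were lower for all 14 members (median -0.71). Calls were 0 over all genes and 3 adjusted over the list alone (adjusted p = 0.000103, adjusted p = 0.177 with an estimated correlation). Members included Tagln (-0.90 ± 0.23) and Acta2 (-1.44 ± 0.44), both of contractile cells. Collagen and matrix genes had a median of -0.27, with 3 of 27 higher and 0 calls either way (adjusted p = 1.29e-06, adjusted p = 0.324 with an estimated correlation). Members included Thbs1 (-2.09 ± 0.56).

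The 1 gene called in averaged fat was 4732419C18Rik, a predicted gene at a mean of 0.417 CPM, which rose by 2.32 ± 0.31 (edgeR adjusted p = 0.0442) and was named after its values were seen. Next were Cnst, a connexin-sorting protein gene, at 0.71 ± 0.10 (adjusted p = 0.0641), the pyruvate dehydrogenase kinase gene Pdk1 at 0.53 ± 0.09 (adjusted p = 0.123) and the transcription factor gene Etv5 at -0.83 ± 0.15 (adjusted p = 0.123). At an unadjusted p under 0.05 there were 2096 genes, DESeq2 called 234 (170 higher), limma-voom 468, a surrogate variable 6, the fit without male vehicle s540 and male CP2 s571 5, and 0 came without a filter, with the stricter filter, with the L number or with the composition covariates. The count was 44 without male CP2 s530, 2 without female CP2 s664 or male CP2 s571, 1 without female CP2 s454 and 0 without any 1 of the other 12 libraries.

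**Figure D2:**
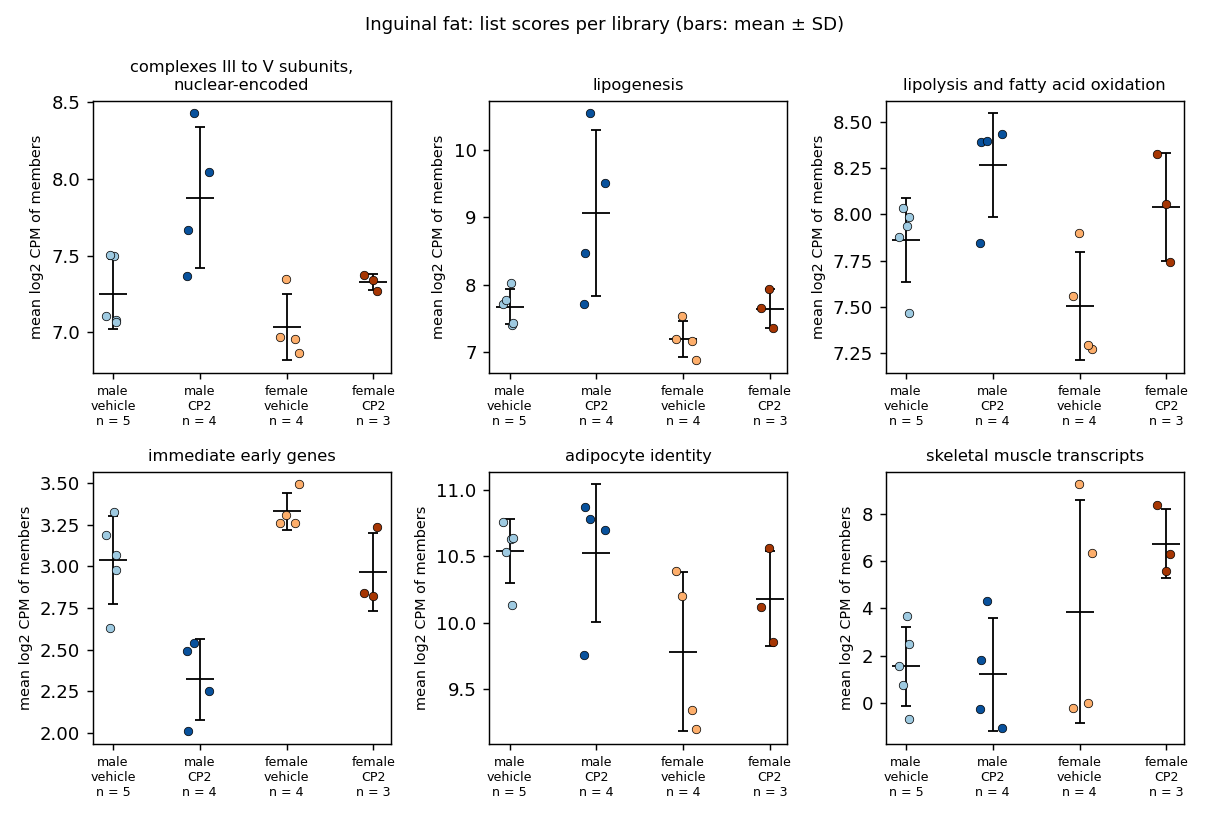
Scores of 6 gene lists (mean log2 CPM of the members, vertical axis) in each of the 16 fat libraries by group, with bars for the group mean and SD. The lipogenesis score ran from 7.71 to 10.55 over the 4 male CP2 libraries, and the immediate early gene score from 2.01 to 2.54 in male CP2 against 2.63 to 3.33 in male vehicle.

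In fat of males the genes called were Msrb1 and Pdk1. Msrb1, a methionine sulfoxide reductase gene (ENSMUSG00000075705, mm10 chromosome 17, 24736642 to 24742778), rose from 76.3 ± 7.95 to 143 ± 18.7 CPM (n = 5 and 4), a log2 change of 0.90 ± 0.12 (edgeR adjusted p = 0.0420). Pdk1, whose product restrains entry of pyruvate into the citric acid cycle (ENSMUSG00000006494, mm10 chromosome 2, 71873224 to 71903858), rose from 75.4 ± 13.9 to 140 ± 8.97 CPM, a log2 change of 0.89 ± 0.12 (adjusted p = 0.0458). Cnst (0.87 ± 0.14, adjusted p = 0.0975) and Mrpl30, of the mitochondrial ribosome (0.58 ± 0.10, adjusted p = 0.108), were next. On the lower side Nnat, an imprinted gene, was at 51.4 to 244 CPM in the 4 CP2 libraries and 797 to 2907 in the 5 vehicle libraries (-3.64 ± 0.60, adjusted p = 0.108), and Etv5 at 9.79 ± 0.263 and 20.4 ± 5.53 CPM (-1.06 ± 0.20, adjusted p = 0.131).

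**Figure D3:**
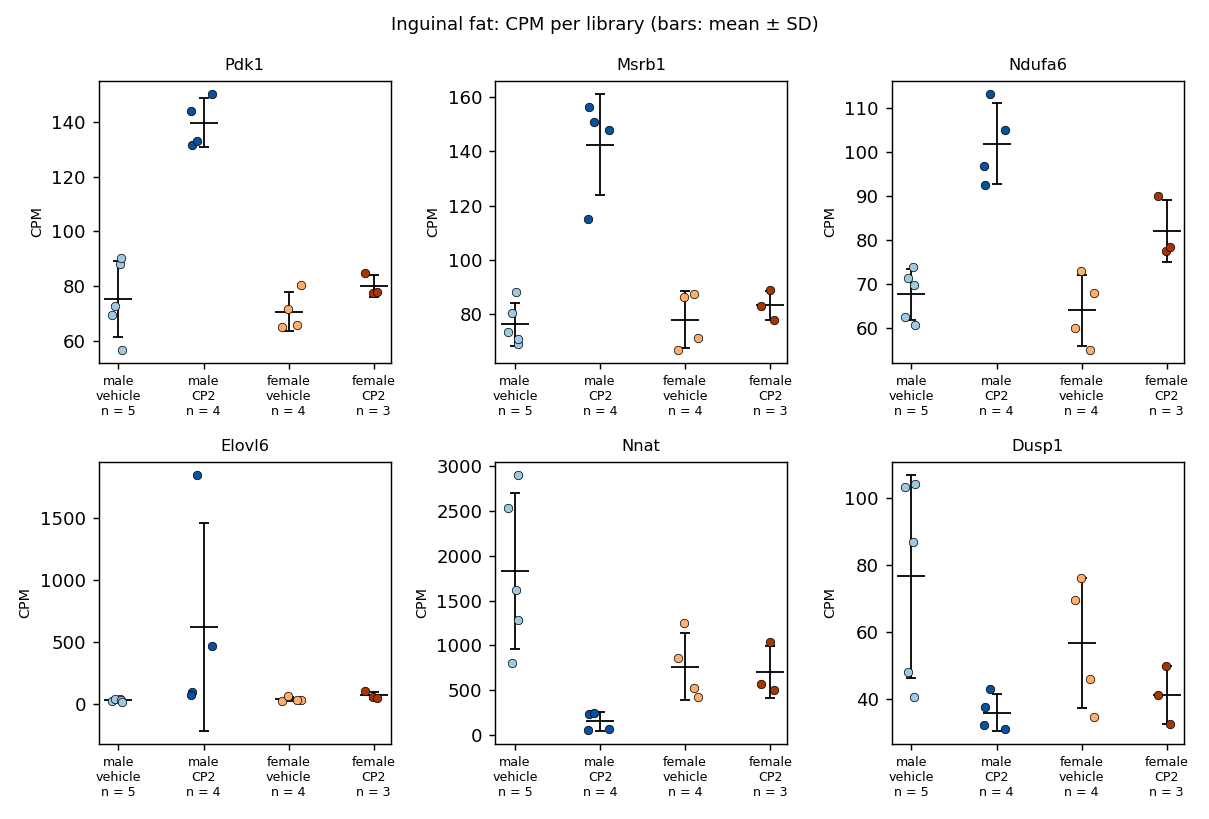
CPM (vertical axis) of 6 genes in each fat library by group, with bars for the mean and SD. Pdk1 averaged 140 CPM in the 4 male CP2 libraries and 75.4 in the 5 male vehicle libraries, and 80.0 and 70.6 in the female groups.

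Complex I subunits were higher in males for 36 of 36 members (median 0.59). Past the threshold were 0 over all genes and 33 adjusted over the list alone (camera adjusted p = 9.38e-25, adjusted p = 0.242 with an estimated correlation). Members included Ndufa6 (0.59 ± 0.10). Subunits of complexes III to V were higher for 35 of 35 (median 0.65). Of these, 0 passed over all genes and 34 adjusted over the list alone (adjusted p = 2.22e-26, adjusted p = 0.242 with an estimated correlation). Members included Uqcr10 (0.94 ± 0.21). Lipogenesis genes were higher for 24 of 24 (median 1.71). Members past the threshold numbered 0 over all genes and 18 adjusted over the list alone (adjusted p = 1.71e-16, adjusted p = 0.242 with an estimated correlation). The fatty acid elongase gene Elovl6 (4.55 ± 0.82) averaged 620 ± 841 CPM with CP2 and 26.4 ± 9.02 with vehicle, and its value was 1851 CPM in male CP2 s571, without which the change was 2.96. The fatty acid synthase gene Fasn (3.89 ± 0.79) averaged 12895 ± 13721 CPM with CP2, with 32208 in s571, and 873 ± 795 with vehicle, and its change was 2.87 without s571. Without that library the medians of complex I, complexes III to V and lipogenesis were 0.36, 0.41 and 1.03. All were still past the threshold at the preset correlation, the only one used in that fit. The adipocyte identity score was 10.53 ± 0.52 and 10.54 ± 0.24 in the CP2 and vehicle groups, a difference of -0.013 that was 0.24 without male CP2 s530.

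Cholesterol synthesis genes were higher for 18 of 19 members (median 0.95). The threshold was passed by 0 over all genes and 7 adjusted over the list alone (adjusted p = 0.000680, adjusted p = 0.685 with an estimated correlation). Members included Nsdhl (1.69 ± 0.46) and Lss (1.20 ± 0.37). This result rested on male CP2 s571, whose score was 6.67 against 4.33 to 4.97 in the other CP2 libraries and 4.39 to 4.67 in vehicle; without it the median was 0.073 (adjusted p = 0.812). Glycolysis genes had a median of 0.51 and a mean of 0.06, with 15 of 21 higher, 1 past the threshold over all genes (Pdk1), and 8 higher and 3 lower adjusted over the list alone (adjusted p = 0.00400, adjusted p = 0.494 with an estimated correlation), and without s571 the median was 0.20 and the call was lost. Hk1, a hexokinase gene, was at -0.54 ± 0.14 and the lactate dehydrogenase gene Ldha at 1.23 ± 0.34. Adipose progenitor markers were lower for all but 3 of 18 (median -0.37). In this list 0 passed over all genes and 1 adjusted over the list alone (adjusted p = 0.000537, adjusted p = 0.242 with an estimated correlation). Members included Anxa3 (-0.86 ± 0.20). All 21 immediate early genes were lower (median -0.70), 0 over all genes and 2 adjusted over the list alone, and the call held with an estimated correlation (adjusted p = 3.78e-08 preset and 0.0240 estimated), with Dusp1 at 36 ± 5.47 CPM with CP2 and 76.5 ± 30.3 with vehicle.

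At an unadjusted p under 0.05 there were 2837 genes in male fat, DESeq2 called 481 (277 higher), limma-voom 703, a surrogate variable 4, the stricter filter 1, and 0 came without a filter, with the L number, with the 2 groups alone or without male vehicle s540 and male CP2 s571. Leaving out male CP2 s530, which had the lowest adipocyte identity score of its group (9.76 against 10.70 to 10.87) and the highest B cell and lymph node (5.60 against 1.38 to 2.92) and T and NK cell scores (5.37 against 1.14 to 1.41), gave 225 genes (213 higher), among them 11 of 24 lipogenesis genes and 8 of 35 of complexes III to V; the count was 2 without male vehicle s621, 1 without female vehicle s442 and 0 without any other library, and without male vehicle s540 and male CP2 s571 the cholesterol median was 0.03.

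In fat of females no gene passed the threshold. Lipolysis and fatty acid oxidation genes were higher for 25 of 26 members (median 0.49). Calls were 0 over all genes and 2 adjusted over the list alone (camera adjusted p = 2.05e-18, adjusted p = 0.134 with an estimated correlation). Ppara, a nuclear receptor that drives genes of fatty acid oxidation, was at 24.4 ± 18.4 CPM with CP2 and 6.72 ± 1.89 with vehicle (n = 3 and 4), a log2 change of 1.86 that was 1.04 without female CP2 s451, and Acadvl was at 0.77 ± 0.22. Subunits of complexes III to V were higher for 34 of 35 (median 0.27, adjusted p = 8.52e-13, adjusted p = 0.395 with an estimated correlation) and lipogenesis genes for 19 of 24 (median 0.47, adjusted p = 1.47e-06, adjusted p = 0.395 with an estimated correlation), both with 0 members past the threshold over all genes or adjusted over the list alone. Thermogenic genes were higher for 14 of 20 (median 0.71). Past the threshold were 0 over all genes and 5 adjusted over the list alone (adjusted p = 1.44e-09, adjusted p = 0.134 with an estimated correlation), with the uncoupling protein gene Ucp1 at 42.0 ± 52.3 CPM with CP2 and 0.719 ± 1.26 with vehicle. The thermogenic score was 4.32 in female CP2 s451, 2.04 and 3.12 in the other female CP2 libraries and 0.93 to 2.57 in female vehicle.

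Transcripts of other tissues varied widely in the female fat pieces. The skeletal muscle score ran from -0.19 to 9.26 in female vehicle libraries and from 5.56 to 8.36 in female CP2 libraries; the list's median was 0.14, its mean -0.07 and its camera direction up, with 14 of 20 members higher and 0 calls either way (adjusted p = 1.18e-12, adjusted p = 0.386 with an estimated correlation). Mammary epithelial transcripts had a median of -1.07, with 4 of 21 higher and 0 calls either way (adjusted p = 1.47e-06, adjusted p = 0.431 with an estimated correlation), and the milk protein gene Wap stood at 765 ± 1463 CPM in vehicle and 2.47 ± 4.28 in CP2 libraries. edgeR called 0 genes, 460 had an unadjusted p under 0.05 where 988.45 would come by chance, DESeq2 called 2, limma-voom 0 and a surrogate variable 1. With the composition covariates the mammary median was 0.51, the muscle median -0.29 and the lipogenesis median 0.09. The covariates include the mammary and muscle scores, so the change of the mammary and muscle medians follows from their construction. The muscle median was -0.27, -0.0022, 2.32 and -0.26 without female vehicle s442, s463, s643 and s443 and 0.60, 0.58 and -1.52 without female CP2 s454, s664 and s451. Without s451 the mammary median was -0.69 and the call was lost, and without s443 it was -0.080.

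The difference of the CP2 effect between the sexes in fat gave 0 genes by edgeR, with 769 at an unadjusted p under 0.05, 3 by DESeq2 and 0 by limma-voom. Lipogenesis genes had a median difference, female minus male, of -1.20, with 2 of 24 positive (camera adjusted p = 5.81e-07, adjusted p = 0.740 with an estimated correlation, fry adjusted p = 0.869), and complexes III to V one of -0.35, with 0 of 35 positive (adjusted p = 3.63e-07, adjusted p = 0.740 with an estimated correlation). Neither had a member past the threshold over all genes or adjusted over the list alone. Msrb1 (-0.81 ± 0.18), Pdk1 (-0.71 ± 0.19) and Nnat (3.52 ± 0.81) had an adjusted p of 1.0, so that the male and female effects on these genes were not shown to differ. Across 15743 genes the male and female changes had a Pearson's r of 0.104 and a Spearman's rho of 0.268, and r was -0.0501 with the L number.

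**Figure D4:**
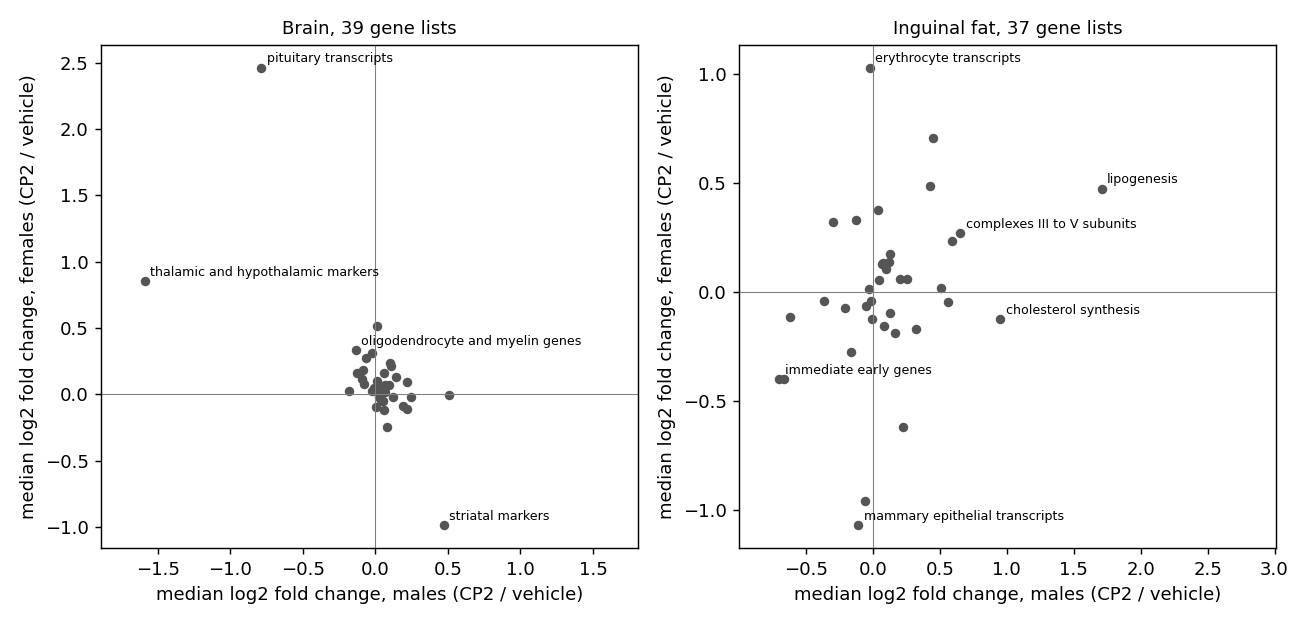
Median log2 change with CP2 of each tested gene list in males (horizontal axis) against females (vertical axis), for 39 lists in brain and 37 in fat, with 1 point per list. In brain the thalamic and hypothalamic list lies at -1.59 in males and 0.85 in females, and in fat the lipogenesis list at 1.71 and 0.47.

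The comparison of tissues asked where CP2 acted differently in fat and brain, averaged over the sexes. Its fit pooled the tissues (coefficient of variation 0.364), which differed when fitted apart (0.170 in brain and 0.500 in fat). It may therefore understate the spread in fat, where the fat fit alone called 1 gene averaged over the sexes. The pooled fit called 34 genes, 20 with a higher and 14 with a lower effect in fat. The higher set included Kcnk3 (1.57 ± 0.26, edgeR adjusted p = 0.0143; mm10 chromosome 5, 30588170 to 30625270), Elovl6 (2.77 ± 0.51, adjusted p = 0.0217; chromosome 3, 129532386 to 129638495), Slc25a1 (1.63 ± 0.32, adjusted p = 0.0368), Cnst (0.67 ± 0.12, adjusted p = 0.0193) and Gucd1 (0.63 ± 0.13, adjusted p = 0.0419). The lower set included Etv5 (-0.97 ± 0.18) and Lrriq1 (-3.08 ± 0.54), both with an adjusted p of 0.0193, and Mest (-3.45 ± 0.67), Unc79 (-2.58 ± 0.51) and Gpr3 (-4.82 ± 0.93), with 0.0362. Complex I genes had a median difference of 0.36, with 36 of 36 positive, 1 called over all genes (Ndufa6, 0.52 ± 0.11) and 22 adjusted over the list alone (camera adjusted p = 2.31e-25, adjusted p = 0.163 with an estimated correlation). Complexes III to V had 0.41, with 34 of 35 positive. Of these, 0 passed over all genes and 29 adjusted over the list alone (adjusted p = 1.01e-27, adjusted p = 0.163 with an estimated correlation).

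Immediate early genes had a median difference of -0.65, with 1 of 22 positive. Members past the threshold numbered 0 over all genes and 4 adjusted over the list alone (adjusted p = 1.49e-05, adjusted p = 0.192 with an estimated correlation). Members included Jun (-0.76 ± 0.20). Collagen and matrix genes had -0.53, with 0 of 27 positive. The threshold was passed by 0 over all genes and 1 adjusted over the list alone (adjusted p = 1.18e-05, adjusted p = 0.341 with an estimated correlation). RLE size factors gave 27 higher and 12 lower, DESeq2 called 405, limma-voom 904, the stricter filter 125 and no filter 9. With the number in the titles as a replicate block, limma-voom called 2, with Cnst at an adjusted p of 0.0321 and the other called genes named here at 0.0779 to 0.130. On the 8 numbers found in both tissues, with the number as a fixed block, edgeR called 0, and the collagen median was -0.17 (adjusted p = 0.138). The count was 214 without s530, 158 without s540, 94 without s621, 83 without s463, 66 without s571, 1 without s451, 3 without s612, 4 without s454, and 7 to 19 without s442, s443, s492, s552, s553, s562, s581, s583, s601, s620, s622, s631, s640, s641, s642, s643, s660 or s664.

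Female and male vehicle libraries were compared as a reference for differences between the sexes. The brain libraries compared had L numbers 1 and 2 in males and 4 to 6 in females. Between these libraries sex cannot be told apart from the L number, except for genes on the sex chromosomes. In brain 12 genes were higher and 7 lower in females, most of them sex-linked. The X-linked genes Eif2s3x (0.58 ± 0.09, edgeR adjusted p = 0.00269), Kdm5c (0.58 ± 0.10, adjusted p = 0.00953) and Kdm6a (0.48 ± 0.08, adjusted p = 0.0133) were higher in females, and Smyd3, a methyltransferase gene, was lower (-0.40 ± 0.08, adjusted p = 0.0450). Disease-associated microglia genes were higher for 20 of 21 members (median 0.36). In this list 0 passed over all genes and 8 adjusted over the list alone (camera adjusted p = 5.96e-10, adjusted p = 0.467 with an estimated correlation). Complement genes were higher for 13 of 14 (median 0.30). Calls were 0 over all genes and 4 adjusted over the list alone (adjusted p = 8.71e-07, adjusted p = 0.467 with an estimated correlation). C1qb averaged 140 ± 21.1 CPM in females and 84.7 ± 23 in males (n = 5 each).

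Senescence and secreted inflammatory factors were higher for 22 of 26 members (median 0.67). Past the threshold were 0 over all genes and 1 adjusted over the list alone (adjusted p = 1.57e-06, adjusted p = 0.476 with an estimated correlation), and their score in female vehicle s640 was 2.21, against 1.26 to 1.39 in the other female vehicle libraries. Glucocorticoid-responsive genes were higher for 14 of 15 (median 0.74), 1 over all genes (Angptl4, 1.40 ± 0.27, adjusted p = 0.0450) and 3 adjusted over the list alone (adjusted p = 1.57e-06, adjusted p = 0.476 with an estimated correlation). DESeq2 called 55 genes and limma-voom 54.

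In fat, 995 genes were higher and 430 lower in vehicle females than in vehicle males. All 21 mammary epithelial transcripts were higher in females, 21 past the threshold over all genes and adjusted over the list alone (camera adjusted p = 1.31e-18, adjusted p = 0.30 with an estimated correlation, fry adjusted p = 0.000968), with a score of 5.90 ± 2.0 in females and -1.58 ± 0.43 in males. Keratin genes of simple epithelium such as Krt18 averaged 148 ± 69.5 CPM in females and 0.640 ± 0.582 in males (n = 4 and 5). Keratinocyte and skin transcripts were higher for 12 of 13 members. Of these, 8 passed over all genes and 10 adjusted over the list alone (adjusted p = 3.43e-07, adjusted p = 0.30 with an estimated correlation, fry adjusted p = 0.000968), with a score of 3.25 ± 0.73 and -0.77 ± 0.36. Adipocyte identity genes were lower for all but 1 of 20 (median -0.65). Members past the threshold numbered 3 over all genes and 5 adjusted over the list alone (adjusted p = 3.43e-07, adjusted p = 0.648 with an estimated correlation). Members included the adipsin gene Cfd (-1.85 ± 0.33, adjusted p = 0.00390).

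Circadian clock genes had a median of -0.71, with 5 of 18 higher, 7 lower past the threshold over all genes, and 8 lower and 1 higher adjusted over the list alone (adjusted p = 0.00104, adjusted p = 0.30 with an estimated correlation, fry adjusted p = 0.0142). Members included Dbp (-2.50 ± 0.43, adjusted p = 0.00302). Proliferation genes were higher for 20 of 20 members (median 2.03). The threshold was passed by 0 over all genes and 15 adjusted over the list alone (adjusted p = 4.74e-06, adjusted p = 0.705 with an estimated correlation). Members included Cdk1 (2.07 ± 0.61). With the composition covariates, chosen after seeing the data, 9 genes were called, against 2714 by DESeq2, 2882 by limma-voom, 2266 with a surrogate variable and 889 (444 higher, 445 lower) with the stricter filter; with those covariates the proliferation median was -1.97 and the adipocyte identity median 0.47. Among these covariates the mammary score was 4.33 to 8.68 in female vehicle and -2.23 to -1.14 in male vehicle libraries. It is nearly tied to sex, so this fit cannot tell sex from tissue content. Leaving out female vehicle s443, male vehicle s621, male vehicle s553 or female vehicle s463 gave 734, 815, 830 and 924 genes.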

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

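The tests of whether a larger share of adipocytes explains the fat results, the region score covariate, the composition covariates, the omission of fat libraries (s530 among them) and the standard errors of the corrected immediate early gene differences were chosen only after the results were seen. The other tests were set down before the values they measure, but after list medians and library scores had been looked at.

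Several libraries lay far from the rest of their group. In brain, female vehicle s640 had scores of 2.21 for senescence and secreted inflammatory factors and 4.06 for complement, male CP2 s581 had 5.60 for disease-associated microglia genes, male vehicle s620 had 1.88 for thalamic and hypothalamic markers, and male CP2 s530 had -0.84 for pituitary transcripts. In fat, female vehicle s643 had a score of 4.81 for mitochondrial biogenesis and AMPK and male vehicle s540 one of 7.31 for glycolysis. Male CP2 s530 had 9.76 for adipocyte identity and 7.85 for lipolysis and fatty acid oxidation, and male vehicle s551 had 7.47 for the latter. For single genes, Elovl6 was at 63.04 CPM in fat female vehicle s643, Fasn at 2270.84 in fat male vehicle s621 and Slc25a1 at 55.71 in fat female vehicle s443. In brain, Ebf3 was at 1.20 CPM in female vehicle s643, Drd1a at 46.57 in female CP2 s664 and Rgs16 at 13.14 in male CP2 s530. In total 16 of 192 pairs of a group and a measure held such a library. These pairs cover the lists and genes named in the report, and fat female CP2, with 3 libraries, was not tested. Chance alone gives about 1 in 20 for normally spread values. The pairs share libraries and are not independent, so that rate is only a guide. Over every list scored, 22 of 267 pairs held such a library. Among them were nuclear-retained long RNAs in fat male vehicle s540 (5.92 against 3.68 to 4.03 in the rest of its group). Others were T and NK cell markers in fat male CP2 s530 (5.37 against 1.14 to 1.41) and hippocampal markers in brain male CP2 s581 (3.83 against 2.12 to 2.45).

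CP2 effects that a direct test set apart between the sexes in brain were those of Ebf3 (2.98) and of 3 lists: oligodendrocyte and myelin genes (0.48), striatal markers (-1.47) and thalamic and hypothalamic markers (1.98), with 1 gene past the threshold in all. The 3 list results were lost with an estimated correlation. In fat, the complexes III to V list (-0.35) and the lipogenesis list (-1.20) differed between the sexes at the preset correlation and not at an estimated one.

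Between tissues 34 genes differed in the fit that pooled brain and fat, which may understate the spread in fat. Those named were Kcnk3 (1.57), Cnst (0.67), Elovl6 (2.77), Slc25a1 (1.63), Gucd1 (0.63), Lrriq1 (-3.08), Etv5 (-0.97), Mest (-3.45), Unc79 (-2.58) and Gpr3 (-4.82). Lists that differed at the preset correlation were complex I (0.36), complexes III to V (0.41), immediate early genes (-0.65) and collagens and extracellular matrix (-0.53). These list results were also lost with an estimated correlation.

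The first pattern weighed was that thalamic, hypothalamic and striatal markers in brain moved in opposite ways with CP2 in males and females. Across 15493 genes outside these lists, the slope on the region score within the 10 vehicle libraries correlated with the female minus male CP2 effect at 0.560, and 1 of 100 shuffles of the score, the real one, was as large (highest other 0.554). Differing regions in the brain pieces may therefore account for it. The slope rests largely on male vehicle s620 (region score -4.62) and female vehicle s643 (-5.01). The rest of their groups lay at -2.44 to -1.34 and -2.53 to -0.785. With the L number as a factor the female minus male difference of the region score was 3.96 against 3.90 without. Its male part rests on male CP2 s581, the 1 male CP2 library whose L number occurs in male vehicle. No fit was possible without s581, so the jackknife used 19 fits and never left s581 out. The jackknife standard error of the distance from the bound was 2.31, so the L number cannot be told apart. The thalamic median was as far from 0 in 2 of 100 splits (real 1.98, highest other -2.42), but the list was picked because it stood out. As many lists as the real 9 were called in 94 of 100 splits, so chance is not excluded. An effect of CP2 that differs by sex was not tested apart from these and stays open.

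The second pattern was that genes of complexes III to V and of lipogenesis were higher with CP2 in fat of males (score differences 0.625 and 1.39). The jackknife standard errors of these differences, added after the results were seen, were 0.279 and 0.702. With the L number as a factor the differences were 0.632 and 1.44, only 1.77 and 1.67 of their standard errors of 0.357 and 0.866. Numbers alone in brackets below are jackknife standard errors of the distance from the bound, 0.5 of the uncorrected difference. Muscle, mammary and B cell scores served as covariates. The mammary score was low in every male library (-2.53 to -1.14), and smooth muscle and Schwann cell content was not covered. With the covariates the differences were 0.575 (0.112) and 1.23 (0.263). This argues against muscle or B cell content as the whole cause, though only narrowly for lipogenesis. The jackknife standard errors of the corrected differences themselves were 0.220 and 0.546. Without male CP2 s571 and with no covariates the differences were 0.441 (0.255) and 0.894 (0.631), so a single library stays open for both. The adipocyte identity score differed by -0.0129, which leaves a larger share of adipocytes open for complexes III to V (0.253). For lipogenesis it argues against such a share (0.281) only with male CP2 s530 included. Without s530 the score differed by 0.24, 0.676 short of the bound (0.401), so a larger share stays open there too. A list median as far from 0 came in 4 of 100 splits for complexes III to V (real 0.65, highest other 0.70) and in 10 of 100 for lipogenesis (real 1.71, highest other 1.93); both lists were picked because they stood out, and 48 of 100 splits called as many lists as the real 15 in fat males, so chance is not excluded for either. An effect of CP2 on these genes was not tested apart from the groups and stays open.

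The third pattern was that immediate early genes were lower with CP2 in fat averaged over the sexes (score difference -0.541). By the bound set down beforehand neither other tissue nor the L number could be told apart. The distances from 0.5 of the uncorrected difference were under 2 of their standard errors (0.136 and 0.141), so that a part stays open. The difference was -0.507 (jackknife standard error 0.186) with the composition covariates and -0.510 (0.180) with the L number. By these standard errors, added later, muscle, mammary or B cell content or the L number is argued against as the cause of the whole difference. Other contents, such as smooth muscle and Schwann cells, were not covariates. The list median was as far from 0 in 1 of 100 splits, the real one (-0.59, highest other -0.41), but the list was picked because it stood out and 31 of 100 splits called as many lists as the real 18, so this alone does not exclude chance. These genes respond to handling within minutes, and time from death to freezing is not given and was not tested. An effect of CP2 stays open.

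Other splits of the libraries into groups of the same sizes were fitted for each count of genes. With a real count of 0 every split gives as many, so the splits decide nothing for brain averaged over the sexes (100 of 100, highest other 34), brain females (100 of 100, highest other 795), fat females (35 of 35, highest other 12) and treatment by sex in fat (100 of 100, highest other 1). Chance cannot be excluded for treatment by sex in brain (6 of 100, real 1, highest other 523) and treatment by tissue (7 of 100, real 34, highest other 1324). Counts as large came in 4 of 100 splits for brain males (real 1, highest other 396), fat averaged (real 1, highest other 2057) and fat males (real 2, highest other 719), but these rest on 1 or 2 genes. Counts at an unadjusted p under 0.05 were as large in 8, 20 and 23 of 100 splits (real 2036, 2096 and 2837, highest other 3090, 5423 and 4530), so chance is not excluded for these 3 either. For female against male vehicle in fat it is excluded at 5 in 100 (1 of 100, real 1425, highest other 881; at an unadjusted p 1 of 100, real 5081, highest other 4956). In brain that comparison had 1 of 100 (real 19, highest other 1) past the threshold. Most of those genes are sex-linked, so this follows from the sex labels and decides nothing for other genes. At an unadjusted p it had 18 of 100 (real 1663, highest other 2819), so chance is not excluded for the wider count. For treatment by sex in brain the unadjusted count was as large in 3 of 100 (real 3131, highest other 3451), against the 6 of 100 above. Some splits gave several times the real count, and whether a structure of the samples other than treatment drives these was not tested. Pearson's r between male and female changes was as far from 0 in 6 of 100 splits in brain (real -0.375, furthest other -0.476). In fat it was so in 55 of 100 (real 0.104, highest other 0.472). Spearman's rho was as far from 0 in 19 of 100 splits in brain and 32 of 100 in fat. Chance is therefore not excluded for either tissue.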

How the results depend on the processing

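Of the alternatives below, the region score covariate, the composition covariates and the fit without fat male vehicle s540 and fat male CP2 s571 were chosen only after the results were seen. Mean depth differed most between brain female CP2 (47.1 ± 4.28 M) and brain female vehicle (40.6 ± 3.36 M), which are compared directly. The number and spread of the fat libraries limit what can be called there. On simulated counts 17.9% of 2-fold changes in fat of males were recovered, against 91.0% in brain. Counts of genes past the threshold were the least stable results, and the cause of each change given here was not tested.

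With RLE size factors every count in the report stayed within 1.5 times its value, and every list kept its direction and its side of the threshold. Over all alternatives other than leaving out a replicate, values of named genes kept direction and side of the threshold in 2004 cases, passed it newly in 259, lost it in 85 and turned in 21. Lists did so in 469, lost the call in 72 and turned in 11. Leaving out replicates, named genes kept both in 4625 cases, passed newly in 137, lost it in 231 and turned in 3, and lists kept both in 981, lost it in 11 and turned in 20.

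With DESeq2 the counts were 82 in brain males, 45 in brain females, 707 for treatment by sex in brain, 55 for sex in brain, 234 in fat averaged, 481 in fat males, 2 in fat females, 3 for treatment by sex in fat, 2714 for sex in fat and 405 for treatment by tissue. The muscle list in fat females (0.19) was no longer past the threshold.

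With limma-voom and quality weights the counts were 787 in brain males, 98 in brain females, 2028 for treatment by sex in brain, 54 for sex in brain, 468 in fat averaged, 703 in fat males, 2882 for sex in fat and 904 for treatment by tissue. In brain averaged the striatal list (-0.10) was no longer past the threshold and complex I turned (0.041), as the pituitary list in brain females (1.54) and adipocyte identity in fat averaged (0.16) fell short of it. In fat females Myh1 (2.95) and Myh2 (2.06) turned. The correlation of the sexes in fat was 0.0558.

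Without a low-count filter the counts were 0 in brain males, 0 for treatment by sex in brain, 0 in fat averaged, 0 in fat males and 9 for treatment by tissue, and complex I in brain averaged turned (0.0042). With the stricter filter they were 0 in brain males, 64 for treatment by sex in brain, 0 in fat averaged, 1 in fat males, 889 for sex in fat and 125 for treatment by tissue, with a correlation of the sexes in fat of 0.178.

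With the L number as a factor the counts were 4 in brain averaged, 6 in brain males, 2 for treatment by sex in brain, 0 in fat averaged and 0 in fat males. Complexes III to V in brain averaged (-0.033) and myelin genes in brain males (0.14) turned, as did Tac1 in brain males (-0.20) and, in fat females, Mb (0.32), Myh1 (2.29), Myh2 (2.17) and Wap (2.18). No longer past the threshold were striatal markers in brain males (0.19), endothelial markers in brain females (0.11), myelin genes for treatment by sex (0.13), adipocyte identity in fat averaged (0.019) and mammary transcripts in fat females (-0.70). The correlation of the sexes was -0.115 in brain and -0.0501, reversed, in fat. In these fits the brain male values rest on male CP2 s581, the 1 CP2 library that shared an L number with male vehicle. In fat females, vehicle s442 alone shared an L number with female CP2 libraries.

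With 1 surrogate variable the counts were 0 in brain males, 327 for treatment by sex in brain, 6 in fat averaged, 4 in fat males, 1 in fat females and 2266 for sex in fat. Complexes III to V in brain averaged (-0.0083), Atp5d in brain averaged (-0.0069) and Myh1 in fat females (0.20) turned, and the correlation of the sexes in brain was -0.454. With only the libraries of the groups compared the counts were 0 in brain males and 0 in fat males.

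With the region score as a covariate the counts were 0 in brain males and 0 for treatment by sex. Striatal markers in males (-0.19), Drd1a (-0.10), Rgs9 (-0.11) and Tac1 (-0.11) in males and thalamic markers in females (-0.11) turned. Lost calls were excitatory synapse (0.064) and myelin genes (-0.085) in males, disease-associated microglia genes (0.12) and pituitary transcripts (0.92) in females, and thalamic (0.28) and striatal (-0.051) markers for treatment by sex. The correlation of the sexes was -0.240. This score is built from the thalamic and striatal lists, so the loss of those lists follows from its construction.

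With the composition covariates the counts were 0 in fat averaged and 9 for sex in fat. In fat females mammary transcripts (0.51), Lalba (0.51), Wfdc18 (0.49), the muscle list (-0.29), Mb (0.13), Myh1 (2.34) and Myh2 (1.77) turned. For sex in fat adipocyte identity (0.47), Cebpa (0.036), the proliferation list (-1.97), Aurka (-0.72), Cdk1 (-0.70) and Tpx2 (-1.54) turned, and the circadian list (-0.72) was no longer past the threshold. Nor were adipocyte identity (0.061) and biogenesis (0.089) in fat averaged and lipogenesis in fat females (0.091), and the correlation of the sexes was 0.175. The composition covariates are built from the muscle, mammary and B cell lists, so the turn of the mammary and muscle lists follows from construction. The mammary score is nearly tied to sex, so in that fit sex cannot be told from tissue content. Without s540 and s571 the counts were 5 in fat averaged and 0 in fat males, cholesterol synthesis in fat males was at 0.032, and the correlation 0.187.

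For treatment by tissue a limma-voom fit with the replicate block (consensus correlation 0.0616) gave 2 genes, and an edgeR fit with the number as a fixed block on the shared numbers gave 0, with collagens at -0.17 and no longer past the threshold. The other 3 lists of that comparison kept their direction and their side of the threshold in both fits. In these fits the tool or the number of libraries changes along with the block.

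Camera with an estimated correlation leaves medians as they are and ended these calls. In brain averaged: endothelial (0.19), striatal (-0.20). In brain males: thalamic (-1.59), striatal (0.47), excitatory synapse (0.22), myelin (-0.14). In brain females: striatal (-0.99), thalamic (0.85), myelin (0.33), disease-associated microglia (0.27), endothelial (0.24), pituitary (2.46). For treatment by sex in brain: thalamic (1.98), striatal (-1.47), myelin (0.48). For sex in brain: disease-associated microglia (0.36), complement (0.30), senescence (0.67), glucocorticoid (0.74). In fat averaged: complex I (0.43), complexes III to V (0.47), lipogenesis (1.12), fatty acid oxidation (0.50), thermogenic (0.50), collagens (-0.27), smooth muscle and Schwann (-0.71), adipocyte identity (0.24), biogenesis (0.11). In fat males: complex I (0.59), complexes III to V (0.65), lipogenesis (1.71), cholesterol (0.95), glycolysis (0.51), progenitor (-0.37). In fat females: fatty acid oxidation (0.49), complexes III to V (0.27), thermogenic (0.71), lipogenesis (0.47), mammary (-1.07), muscle (0.14). For treatment by sex in fat: complexes III to V (-0.35), lipogenesis (-1.20). For sex in fat: mammary (7.84), keratinocyte (3.14), adipocyte identity (-0.65), circadian (-0.71), proliferation (2.03). For treatment by tissue: complexes III to V (0.41), complex I (0.36), immediate early genes (-0.65), collagens (-0.53). Immediate early genes in fat averaged and in fat males stayed past the threshold.

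Leaving out each replicate in turn gave, from lowest to highest, 0 to 156 genes in brain males, 0 to 18 in brain females, 0 to 809 for treatment by sex in brain, 0 to 44 in fat averaged, 0 to 225 in fat males, 734 to 1853 for sex in fat and 1 to 214 for treatment by tissue. The correlation of the sexes ran from -0.481 to -0.209 in brain and from 0.033 to 0.151 in fat. In brain averaged, complex I ran from -0.024 to 0.032, complexes III to V from -0.025 to 0.033 and striatal markers from -0.31 to -0.061; myelin genes in males ran from -0.24 to -0.070 and pituitary transcripts in females from 2.05 to 4.05. In fat, adipocyte identity averaged ran from 0.11 to 0.34, cholesterol in males from 0.073 to 1.22 and glycolysis in males from 0.20 to 0.68. In fat females mammary transcripts ran from -1.54 to -0.080, the muscle list from -1.52 to 2.32, Mb from -3.01 to 1.31, Myh1 from -2.17 to 5.08 and Myh2 from -2.57 to 4.49; the last 3 turned without female vehicle s643.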

Other observations

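Which lists are described here was chosen only after the results were seen, and no further test was run for this part. In fat, the nuclear subunits of the respiratory chain and the genes of fatty acid synthesis and oxidation lay on the same side with CP2, and in brain the medians of the subunits of the chain lay near 0. Pdk1 and Msrb1 in fat of males were the genes above 1 CPM that passed the edgeR threshold in the CP2 comparisons within fat.

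Pituitary transcripts were measured in some brain pieces: their score averaged 0.47 ± 1.86 (SD, n = 5) in female CP2, -1.28 ± 1.10 in female vehicle, -2.80 ± 1.12 in male CP2 and -2.43 ± 1.20 in male vehicle libraries. In fat, B cell scores averaged 4.69 ± 1.71 in female CP2 (n = 3), 4.07 ± 2.20 in female vehicle (n = 4), 2.88 ± 1.94 in male CP2 (n = 4) and 3.41 ± 1.66 in male vehicle libraries (n = 5).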
